A study of Mus musculus with 77 samples.

How the data were processed

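Processed files were used as deposited. The 4 expression tables give TPM (read counts scaled for transcript length and to a common library total) for 24940 RefSeq transcripts, 1 per gene symbol, which the authors computed with HOMER from reads aligned with STAR to mm10, per the submitters' processing notes. The 10 peak lists give for each 200 bp interval a score, which per the file headers is HOMER's tag count scaled to 10 M (mega) tags. Per the same headers peaks were called on tag directories that combine the replicates, at least 4-fold over input and over the local background and at a false discovery rate of 0.001, from reads aligned with Bowtie2 per the submitters' processing notes. Versions of STAR, HOMER and Bowtie2 are not given in the sources used here. Raw reads and tag-level coverage were not analysed here, so reads were not recounted and peaks were not recalled.

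Columns were matched to samples by genotype, exposure and replicate number in the column names and titles, and all columns could be matched to a group. The 7 B6 lung columns are identical in both lung tables for all 24396 transcripts that the tables share, so comparisons of KO with B6 and of DBA with B6 use the same controls. They are not independent of each other, and they are not laid over each other. KO BMDM ChIP-seq samples were grouped by their title. TPM multiplied by transcript length was close to a whole multiple of a library constant for at least 99.4% of values (tolerance 0.15), which gave the estimated reads per library. Sums of TPM over the listed transcripts were 529199 to 605692, so the tables do not hold all transcripts that entered the authors' scaling.

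TPM were transformed to log2(TPM + 1), the unit in which fold changes are given. Genes with at least 1 TPM in as many libraries as the smallest group holds were tested, which left 15614, 15623, 14636 and 12320 genes in the table of B6 and KO lungs, the table of B6 and DBA lungs, set 2 and BMDM. Each table was fitted with limma 3.58.1 in R 4.3.3 with 1 mean per group, a variance trend and all its groups in the fit. Benjamini-Hochberg adjustment was done over all genes tested within each of 19 comparisons, and a gene was called at adjusted p < 0.05. The interactions are differences of differences, (KO hyperoxia minus KO room air) minus the same in B6, and likewise for DBA. No further scaling was applied, because TPM are already scaled per library. Since TPM are shares, a few very abundant transcripts lower the values of all others in the same library. The alternatives were quantile normalization, another pseudocount, no filter on low values, a minimum absolute log2FC of 1, only the groups of a comparison in the fit, each library left out in turn, date code or sex as a term and as a subset, and replicate number as a block. Replicate numbers in BMDM and set 2 were not used as pairs because the labels give them only as numbers. Correlation between the deviations of libraries with the same number was -0.05 in KO BMDM and 0.08 in DBA BMDM, and 0.38 between the B6 BMDM libraries with the same mark.

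In all, 25 gene lists were written from general knowledge before the data were examined, and 23 of them with enough members were tested with camera in limma at a preset inter-gene correlation of 0.01. It compares the genes of a list with all other genes tested. Camera with an estimated correlation and fry were run beside it. Of 383 list tests over the 19 comparisons 146 passed with the preset correlation and 11 with the estimated one, so list results are given with both. The glucocorticoid, ciliated, secretory airway, stromal and mast-cell lists were added after the values were seen. Results with those lists are in the text as such. Ciliated cell genes did not pass as a list in the first B6 lungs (camera adjusted p = 0.138), and secretory airway genes rose there in 3 of 5 cases (camera adjusted p = 0.0151, and 0.229 with an estimated correlation). Stromal genes did not pass there (camera adjusted p = 0.877).

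Genes are named by a rule fixed before the data were examined. Trem2, Trp53 and Cdkn1a are named in all comparisons. Added to them are up to 6 largest rises and 6 largest falls among called genes whose groups do not overlap and whose mean is at least 5 TPM in the higher group, without predicted genes, and from each list up to 4 called members with the largest absolute log2FC. For interactions the overlap criterion was not applied. For peak lists it covers the 5 highest peaks within 10 kb of a start site, of which some are named, and all at Cdkn1a, Mdm2 and Trem2. Fkbp5, Zbtb16, Gdf15, Timp1 and Top2a were chosen for the plots after their values were seen.

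Peaks were assigned to RefSeq start sites within 10 kb, with 1 kb and 50 kb as alternatives, and intersected with bedtools 2.31.1. Start sites were those listed in the expression tables. The share of p53 targets with a peak was compared with that of the other genes tested by a two-sided Fisher's exact test in SciPy 1.17.1, adjusted over the 10 lists. Python 3.11.15 and matplotlib 3.10.9 were used for peaks and figures. As a chance check, the libraries of each lung comparison were divided in all other ways that keep group sizes, up to 100, and the calls counted.

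The procedure was tested on simulated data in which 200 genes were changed by a known amount on the observed spread. In the design of the B6 lungs 66% of genes with a true log2FC of 0.5 and 96% of those with 1 were recovered, with 5.24% false calls. Set 2 recovered 6% and 58% (3.70% false), B6 BMDM 60% and 90% (2.23%), and the KO minus B6 lung interaction 24% and 74% (5.13%).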

Results

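Newborn mice kept in high oxygen develop lung injury with poorly formed alveoli, and the series asked how the myeloid receptor gene Trem2 and the transcription factor p53, the product of Trp53, take part in it. Mice of 3 genotypes were compared: C57BL/6J (B6), a Trem2 knockout (KO) and the inbred strain DBA/2J (DBA). They were kept in room air or in 75% oxygen (hyperoxia) from the first 24 h after birth to postnatal day 14. Lung poly(A) RNA was sequenced in 4 room-air and 3 hyperoxia libraries of B6, and in 4 and 4 libraries each of KO and DBA. A second set of B6 lungs (set 2) held 2 room-air and 3 hyperoxia libraries and was tested on its own. Bone-marrow-derived macrophages (BMDM) were kept for 24 h in room air or in 95% oxygen, with 2 RNA libraries in each of the 6 groups. Binding of p53 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq), and the authors' 6 lung and 4 BMDM peak lists each pool the replicates of a group. Expression is given as the authors' TPM (read counts scaled for transcript length and library size), mean ± SD over the libraries of a group. The log2 fold change (log2FC) is a difference between group means of log2(TPM + 1), so it is smaller than the ratio of TPM for weakly expressed genes, and adjusted p is from limma over all genes tested. Estimated depth was 18.5 to 41.1 M (mega) reads per library in the B6 and KO lungs, 12.5 to 41.1 M reads in the table of B6 and DBA lungs, 7.08 to 8.04 M reads in set 2 and 14.6 to 47.0 M reads in BMDM. The labels do not say that replicates are separate animals, so p-values measure the spread between samples, which may be technical.

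Trem2 (NM_001272078, chromosome 17, 48346401 to 48352276 on mm10) encodes a lipid-sensing receptor of macrophages and microglia. Its level was low in whole lung and high in BMDM. In B6 lung it measured 3.36, 3.45, 3.73 and 2.14 TPM in the room-air libraries and 8.48, 5.97 and 9.85 TPM in hyperoxia. Transcript was still detected in the KO lungs, at 1.13, 1.05, 2.75 and 1.45 TPM in room air and 1.97, 2.67, 1.96 and 2.24 TPM in hyperoxia. DBA lungs held 1.43, 2.38, 1.204 and 4.28 TPM in room air and 4.75, 3.09, 2.67 and 5.57 TPM in hyperoxia, and set 2 held 3.79 and 3.85 TPM in room air and 7.61, 8.43 and 10.7 TPM in hyperoxia. In BMDM, B6 cultures read 962 and 948 TPM in room air and 917 and 908 TPM in hyperoxia. KO cultures read 236 and 239 TPM and 252 and 243 TPM, and DBA cultures 1096 and 1030 TPM and 1021 and 1007 TPM. KO and B6 libraries were therefore fully separated in BMDM (237 ± 2.81 against 955 ± 10.2 TPM in room air, log2FC -2.003, adjusted p = 2.35e-08) and in hyperoxic lung (2.21 ± 0.333 against 8.1 ± 1.97 TPM, log2FC -1.49, adjusted p = 8.43e-05). In room-air lung the highest KO library lay above the lowest B6 library, and the difference did not pass (log2FC -0.71, adjusted p = 0.262). Which part of the gene is deleted is not given in the sources used here.

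**Figure D1:**
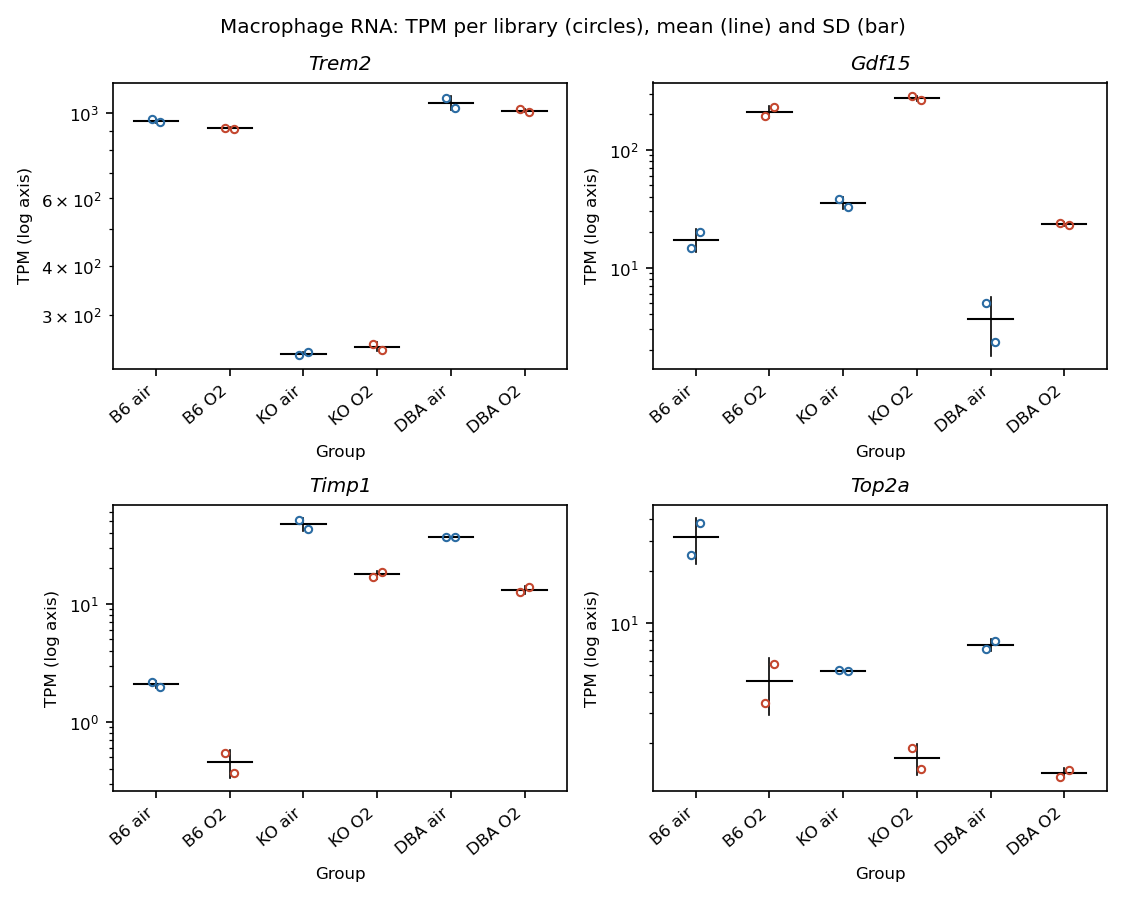
TPM on a log axis in every BMDM library (circles) of the 6 groups for Trem2, Gdf15, Timp1 and Top2a, with the group mean as a line and the SD as a bar (n = 2 per group). Trem2 reads 236 to 252 TPM in KO cultures and at least 908 TPM in the others, and the stress cytokine gene Gdf15 is higher in oxygen in each genotype.

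The first question was what oxygen does to the wild-type newborn lung. In B6, hyperoxia raised targets of p53, the only list that passed with the preset and with an estimated correlation between genes. With the preset correlation alone, genes of the antioxidant response and a group of genes known to respond to glucocorticoid hormones rose, and lymphocyte genes and genes of MHC class II and dendritic cells fell. Cdkn1a (NM_007669, chromosome 17, 29093769 to 29100722), the p53 target that encodes the cell-cycle inhibitor p21, showed the largest rise, from 25.7 ± 3.05 to 372 ± 50.9 TPM (log2FC 3.80 ± 0.11 SE, adjusted p = 1.09e-11), with n = 4 room-air and n = 3 hyperoxia libraries. In all, 6662 of 15614 genes passed at adjusted p < 0.05, of which 2595 rose and 4067 fell. Of 35 divisions of the same libraries into groups of these sizes, none but the real one gave more than 2787 calls. Chance is therefore an unlikely source of the count. Groups did not overlap for 43.7% of the genes tested, where chance gives 5.71%.

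Next to Cdkn1a stood Zbtb16, a zinc-finger transcription factor gene induced by glucocorticoids, which rose from 6.99 ± 4.64 to 85.1 ± 8.93 TPM (log2FC 3.59 ± 0.41 SE, adjusted p = 6.7e-06). Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor and is a classic target of it, rose from 5.92 ± 1.04 to 74 ± 14.6 TPM (log2FC 3.43 ± 0.18 SE, adjusted p = 6.66e-09). Arg2, the mitochondrial arginase gene, rose with log2FC 3.48, Spink5, a protease inhibitor gene of barrier epithelia, with log2FC 2.90 and Myh6, a cardiac myosin gene, with log2FC 2.69. Myh6 varied widely between libraries of a group (16.9 ± 15.8 TPM in hyperoxia), and its call was lost under quantile normalization. The largest fall was in Crabp1, which encodes a retinoic-acid-binding protein, from 50.7 ± 19.9 to 1.31 ± 0.0681 TPM (log2FC -4.40 ± 0.24 SE, adjusted p = 9.54e-09). Fabp1, a fatty-acid-binding protein gene, was listed at 0 in all hyperoxia libraries and at 7.7 ± 3.61 TPM in room air. Other large falls were in Havcr1 (log2FC -2.73), in Ntrk2, which encodes a neurotrophin receptor (log2FC -2.69), and in the amino-acid transporter gene Slc7a10 (log2FC -2.62). Trem2 rose (log2FC 1.12, adjusted p = 0.000651), while Trp53 itself fell from 37.6 ± 3.67 to 24 ± 4.5 TPM (log2FC -0.64 ± 0.11 SE, adjusted p = 0.000338).

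Of the p53 target genes in B6 lung, 25 of 40 rose and 4 fell (25 and 4 adjusted over the list alone, median log2FC 0.75, camera adjusted p = 1e-10, and 0.000434 with an estimated correlation). Eda2r, a death-domain receptor gene, rose by log2FC 2.52, the spindle protein gene Psrc1 by 2.41 and Trp53inp1, which encodes a stress protein of autophagy and cell death, by 2.16. Of the NRF2 antioxidant genes, 19 of 23 rose and 1 fell (20 and 2 adjusted over the list alone, camera adjusted p = 4.65e-12, and 0.101 with an estimated correlation). Gpx2, a glutathione peroxidase gene of epithelia, rose from 4.24 ± 0.782 to 30.2 ± 3.48 TPM (log2FC 2.58 ± 0.17 SE, adjusted p = 6.58e-08). The enzyme genes Nqo1 and Gclc followed with log2FC 2.08 and 1.94. Markers of the transitional alveolar epithelium, a state between type 2 and type 1 cells, moved the same way: 8 of 12 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.00195, and 0.477 with an estimated correlation), among them the keratin gene Krt18 (log2FC 1.34). Among lymphocyte genes 5 of 11 (5 adjusted over the list alone) fell (camera adjusted p = 0.0118, and 0.477 with an estimated correlation), among them the B-cell gene Ms4a1 (log2FC -2.32). Of the genes for MHC class II and dendritic cells 8 of 11 (8 adjusted over the list alone) fell (camera adjusted p = 0.0145, and 0.442 with an estimated correlation), including Ciita, the master regulator of class II expression (log2FC -1.43). Lyve1, a hyaluronan receptor gene of lymphatic endothelium, rose from 153 ± 33.7 to 582 ± 209 TPM (log2FC 1.89 ± 0.19 SE, adjusted p = 2.86e-06). Kdr, the main receptor gene for vascular endothelial growth factor, fell from 152 ± 22.5 to 84 ± 15 TPM (log2FC -0.85 ± 0.13 SE, adjusted p = 0.000129).

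The glucocorticoid-responsive genes were grouped into a list after the values had been seen, so their test describes a pattern already noticed. Of these genes, 19 of 22 rose and 0 fell in B6 (median log2FC 1.43, camera adjusted p = 1.19e-13, and 0.062 with an estimated correlation). Sex and date code differed within the B6 groups, and no paired analysis was possible because lung column numbers restart within each date code and the labels do not say which column is which titled replicate. Libraries of the first date code alone gave 5566 calls, and males alone gave 5136.

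The same oxygen exposure was then tested in lungs without intact Trem2. In KO lungs p53 targets, antioxidant genes and genes of the integrated stress response rose, and 3079 genes passed (1657 rose, 1422 fell, n = 4 and 4). Cdkn1a rose from 38.9 ± 4.93 to 262 ± 20 TPM (log2FC 2.73 ± 0.11 SE, adjusted p = 5.26e-10). The glucocorticoid-responsive genes did not rise: Zbtb16 fell from 27.4 ± 15.2 to 2.72 ± 0.392 TPM (log2FC -2.75 ± 0.38 SE, adjusted p = 0.000194). No other split of the 8 libraries gave more than 1 call, which makes chance unlikely. Among libraries of the third date code, the only code with both exposures, 1905 genes passed.

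The largest rises in KO lung were in the p53 targets Psrc1 (log2FC 3.51, adjusted p = 1.44e-07) and Eda2r (log2FC 3.28, adjusted p = 6.72e-10), in Spink5 (log2FC 2.88), in Gpx2 (log2FC 2.83) and in Pigr, the receptor gene that carries immunoglobulin A across epithelia (log2FC 2.64). Crabp1 fell by log2FC -3.38 and the drug-metabolizing enzyme gene Cyp2e1 by -2.85. Ntrk2 followed with -2.76 and the lysozyme gene Lyz1, which marks some secretory epithelia, with -2.17. Of the p53 target genes 25 of 40 rose and 2 fell (27 and 3 adjusted over the list alone, camera adjusted p = 1.16e-15, and 6.78e-05 with an estimated correlation), and of the NRF2 genes 21 of 23 (22 adjusted over the list alone) rose (camera adjusted p = 1.08e-19, and 0.0141 with an estimated correlation). For the integrated stress response, the ATF4 program of amino-acid and protein-folding stress, 11 of 14 (11 adjusted over the list alone) genes rose (camera adjusted p = 2.41e-09, and 0.0122 with an estimated correlation), led by Trib3 (log2FC 1.29) and Atf3 (log2FC 1.16). Senescence and secretory genes rose in 9 of 17 (10 adjusted over the list alone) cases (camera adjusted p = 1.02e-06, and 0.0154 with an estimated correlation). Gdf15, a stress cytokine gene induced by p53 and ATF4, rose from 0.613 ± 0.203 to 6.58 ± 1.81 TPM (log2FC 2.21 ± 0.18 SE, adjusted p = 1.45e-06). Inflammatory cytokine genes rose in 8 of 17 (8 adjusted over the list alone) cases (camera adjusted p = 0.00259, and 0.124 with an estimated correlation), with the neutrophil chemokine gene Cxcl5 (log2FC 2.60, adjusted p = 2.23e-06) and the monocyte chemokine gene Ccl2 (log2FC 1.99, adjusted p = 0.000166) ahead. Cell-cycle genes rose in 19 of 30 (25 adjusted over the list alone) cases (camera adjusted p = 4.14e-11, and 0.0982 with an estimated correlation). Among endothelial genes 2 of 17 rose and 9 fell (2 and 11 adjusted over the list alone, camera adjusted p = 0.000152, and 0.076 with an estimated correlation): the vascular receptor genes Ptprb (log2FC -0.85), Aplnr (log2FC -0.77) and Tek (log2FC -0.74) were lower in oxygen. Pdgfra, which marks the fibroblasts that build alveolar septa, fell from 112 ± 12.5 to 34.3 ± 6.66 TPM (log2FC -1.69 ± 0.15 SE, adjusted p = 2.53e-06). Trem2 (log2FC 0.35, adjusted p = 0.236) and Trp53 (log2FC 0.23, adjusted p = 0.131) did not pass in KO lung.

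Whether the response to oxygen depends on genotype was tested as the difference between the KO and B6 responses, with a positive value meaning a higher response in KO. A difference was found for 3955 genes, of which 2553 were positive and 1402 negative. Quantile normalization gave 50.9% positive against 64.6% without it, so the direction of the total rests on scaling. Relabelled libraries gave up to 3617 calls in 100 tries, so the real count stood above them by a small margin only. Genotype is confounded with date code. In males alone 2896 genes differed. Set 2 was put beside these calls after they were seen. Set 2 moved the same way as the first B6 lungs for 49.1% (1547 of 3152) of their calls where KO and B6 differed. Where they did not, it was 80.6% (2691 of 3338). Of 119 differing genes called in both B6 sets, 76 moved the same way. The count is thus not read as genotype alone. Zbtb16 had the largest negative difference (log2FC -6.34, adjusted p = 5.39e-06), followed by Fkbp5 (log2FC -4.01, adjusted p = 1.54e-07), which measured 8.86 ± 1.21 TPM in hyperoxic KO lung and 74 ± 14.6 TPM in hyperoxic B6 lung.

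Pdk4, which encodes a kinase that holds back glucose oxidation and is induced by fasting and glucocorticoids, differed by -3.77 and the stress-induced actin-binding protein gene Fam107a by -3.60. The largest positive differences that belong to protein-coding genes were in the orphan nuclear receptor gene Nr4a1 (log2FC 3.65, adjusted p = 3.91e-05), in the homeobox gene Meox2 (log2FC 2.42), in Cxcl5 (log2FC 2.39) and in Il33, the gene of an alarmin cytokine (log2FC 2.36). Cdkn1a rose less in KO than in B6 (difference -1.07, adjusted p = 0.0002), and Trp53 differed by 0.87 (adjusted p = 0.000867). The Trem2 difference of -0.77 did not pass (adjusted p = 0.0642). Glucocorticoid-responsive genes were lower in the KO response in 18 of 22 cases (median log2FC -1.60, camera adjusted p = 3.69e-19, and 0.0219 with an estimated correlation). Interferon-response genes were higher in 10 of 20 (12 adjusted over the list alone) cases (camera adjusted p = 0.00156, and 0.917 with an estimated correlation), including Oasl2 (log2FC 1.93). As a list the p53 targets gave no difference: 11 were higher and 7 lower of 40 (12 and 7 adjusted over the list alone), with a positive median of 0.24 and a negative direction in camera (adjusted p = 0.868).

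In room air 12 of 15614 genes differed between KO and B6 lungs (8 higher and 4 lower in KO). In limma 1320 had unadjusted p < 0.05. No other split gave more than 1 call. Males alone, where genotype follows date code, gave 104 calls (47 higher, 57 lower). The second date code alone, where genotype follows sex, gave 0 with limma (1073 at unadjusted p < 0.05). Nr4a3, an activity-induced nuclear receptor gene, was higher in KO at 6.95 ± 1.51 against 1.55 ± 0.682 TPM (log2FC 1.67, adjusted p = 0.0211). Hif3a, a hypoxia-pathway gene that also responds to glucocorticoids, was higher by log2FC 1.29 and Fkbp5 by 1.09. Hlx, a homeobox gene, was lower by -0.71 and Ndn, the imprinted growth-suppressor gene, by -0.49. None of these 5 genes passed with only KO and B6 room-air lungs in the fit. Cdkn1a (log2FC 0.58, adjusted p = 0.0626) and Trp53 (log2FC -0.10) did not pass. Glucocorticoid-responsive genes were higher in 2 of 22 cases (17 adjusted over the list alone, median log2FC 0.55, camera adjusted p = 1.07e-28, and 0.00523 with an estimated correlation). In hyperoxia, 5814 genes differed (3435 higher and 2379 lower in KO), with up to 1432 calls in other splits. There genotype and date code go together and cannot be told apart.

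Zbtb16 in hyperoxia was lower in KO at 2.72 ± 0.392 against 85.1 ± 8.93 TPM (log2FC -4.54, adjusted p = 1.88e-06) and Fkbp5 at 8.86 ± 1.21 against 74 ± 14.6 TPM (log2FC -2.92, adjusted p = 7.02e-08). Arg2 was lower by log2FC -2.24 and Fbxo32, a ubiquitin-ligase gene of muscle wasting and a glucocorticoid target, by -2.09. Il33 (log2FC 2.50, adjusted p = 2.32e-05), Nr4a1 (log2FC 2.37, adjusted p = 3.7e-05) and Cxcl5 (log2FC 2.16, adjusted p = 8.63e-06) were higher in KO. Trp53 was higher in KO as well (log2FC 0.77, adjusted p = 9.56e-05), and Cdkn1a lower (log2FC -0.49, adjusted p = 0.00318). Inflammatory cytokine genes were higher in 8 of 17 (9 adjusted over the list alone) cases (camera adjusted p = 0.00946, and 0.913 with an estimated correlation).

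Set 2 asked whether the B6 response recurs in separate lungs, and it gave 723 calls (458 rose, 265 fell). The p53 and antioxidant lists passed upward again with the preset correlation, and no list passed with an estimated one. The glucocorticoid-responsive genes did not rise as a list. Retnla, a gene of alternatively activated macrophages and airway epithelium, rose from 19.6 ± 6.74 to 790 ± 618 TPM (log2FC 4.99 ± 0.54 SE, adjusted p = 0.00232), with n = 2 and 3. Cdkn1a rose from 25.4 ± 4.67 to 237 ± 6.77 TPM (log2FC 3.18 ± 0.13 SE, adjusted p = 2.94e-05) and Trem2 rose from 3.82 ± 0.0375 to 8.92 ± 1.61 TPM (log2FC 1.03 ± 0.18 SE, adjusted p = 0.0151).

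Tff2, a mucosal repair peptide gene, rose from 0.134 ± 0.189 to 23.7 ± 9.43 TPM (log2FC 4.39 ± 0.28 SE, adjusted p = 0.000218). Scgb3a1 of secretory airway cells (log2FC 4.53), Pigr (log2FC 3.99), Cxcl5 (log2FC 3.91) and Psrc1 (log2FC 3.87) made up the other large rises. Crabp1 fell by log2FC -2.53. Other large falls there were in microRNA and small nucleolar RNA genes, which poly(A) libraries measure poorly. Of the p53 target genes 20 of 40 rose and 1 fell (24 and 2 adjusted over the list alone, camera adjusted p = 1.11e-13, and 0.106 with an estimated correlation), and of the NRF2 genes 14 of 23 (21 adjusted over the list alone) rose (camera adjusted p = 8.85e-18, and 0.106 with an estimated correlation). Endothelial genes fell in 5 of 17 (10 adjusted over the list alone) cases (camera adjusted p = 1.22e-05, and 0.285 with an estimated correlation), with Aplnr at log2FC -1.37. The glucocorticoid-responsive genes had median log2FC -0.52, and 2 of 22 rose and 6 fell (camera adjusted p = 1.03e-05, and 0.533 with an estimated correlation). Removing room-air replicate 2, whose share of hemoglobin transcript Hbb-b1 reached 5.26% of TPM, left 123 calls. Trp53 did not pass in set 2 (log2FC 0.35, adjusted p = 0.14), with a sign opposite to that in the first B6 lungs.

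DBA mice were studied as a strain that differs from B6 across the genome. In DBA lung, hyperoxia raised cell-division genes most broadly, though no list passed there with an estimated correlation, and 4841 of 15623 genes passed (2909 rose, 1932 fell, n = 4 and 4). With Scgb1a1 left out and libraries rescaled 2109 rose and 2568 fell, so the larger side is not a finding. Cdkn1a rose only from 102 ± 37 to 168 ± 34.1 TPM (log2FC 0.76 ± 0.22 SE, adjusted p = 0.0163), from a room-air level already high, and did not pass with only DBA lungs in the fit. Mcpt2, a mast-cell protease gene, rose from 2.19 ± 1.35 to 27.5 ± 9.65 TPM (log2FC 3.18 ± 0.28 SE, adjusted p = 9.6e-06). Other splits of these libraries gave at most 105 calls, which excludes chance. The fourth date code gave 1788 calls and the fifth 4448. With no other group in the fit limma gave 0 for the fourth (3947 at unadjusted p < 0.05) and 3640 for the fifth.

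Every one of the cell-cycle genes rose in DBA lung: 30 of 30 (30 adjusted over the list alone, median log2FC 1.26, camera adjusted p = 7.43e-21, and 0.293 with an estimated correlation). Cma1, the mast-cell chymase gene, rose by log2FC 2.71 and Psrc1 by 2.42. Tnfrsf25, a death receptor gene of lymphocytes, fell by log2FC -2.25, the clock repressor gene Ciart by -2.16, Crabp1 by -2.06 and Nr4a3 by -2.005. The heat-shock gene Hspa1b fell by -2.19, and its reads cannot be told from those of its near-identical neighbor Hspa1a. Of the p53 target genes 16 of 40 rose and 6 fell (17 and 6 adjusted over the list alone, camera adjusted p = 0.025, and 0.514 with an estimated correlation). NRF2 genes rose in 17 of 23 (18 adjusted over the list alone) cases (camera adjusted p = 7.04e-07, and 0.514 with an estimated correlation). Alveolar type 2 genes, which make surfactant, rose in 8 of 11 cases and fell in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.00473, and 0.514 with an estimated correlation). Neutrophil genes rose in 5 of 10 (6 adjusted over the list alone) cases (camera adjusted p = 0.0173, and 0.68 with an estimated correlation), with S100a9, a subunit gene of calprotectin, at log2FC 1.68. Mast-cell genes, listed after the values were seen, rose in 6 and fell in 3 of 9 cases (camera adjusted p = 0.0419, and 0.418 with an estimated correlation). Trem2 (log2FC 0.64, adjusted p = 0.0754) and Trp53 (log2FC 0.25, adjusted p = 0.154) did not pass.

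The DBA and B6 responses differed for 4563 genes (3126 positive, 1437 negative). Quantile normalization gave 53.1% positive against 68.5%, and a median of all genes of 0.00 against 0.11. In males alone 2940 genes differed, and a relabelling with only 5 of 15 labels right gave 5533 calls. Moving labels within an exposure can bring strain differences into that count. Set 2 moved as the first B6 lungs did for 55.6% (1720 of 3095) of their calls where DBA differed. Where it did not, it was 74.2% (2508 of 3382). Of 176 differing genes called in both sets, 132 moved the same way. Zbtb16 (log2FC -4.48, adjusted p = 0.000558), Pdk4 (log2FC -3.56, adjusted p = 8.22e-05), Fkbp5 (log2FC -3.44, adjusted p = 0.000211) and Klf15, a metabolic regulator gene and glucocorticoid target (log2FC -3.18), responded less in DBA. Cdkn1a differed by -3.04 (adjusted p = 6.01e-05) and Trp53 by 0.89 (adjusted p = 0.00341). The fatty-acid transporter gene Slc27a6 (log2FC 3.37) and the replicative helicase subunit gene Mcm2 (log2FC 2.19) responded more. Cell-cycle genes were higher in the DBA response in 25 of 30 (27 adjusted over the list alone) cases (camera adjusted p = 1.2e-10, and 0.671 with an estimated correlation). Of the p53 targets 3 were higher and 11 lower of 40 (3 and 11 adjusted over the list alone, camera adjusted p = 0.000962, and 0.435 with an estimated correlation). Glucocorticoid-responsive genes were lower in 20 of 22 cases (median log2FC -2.33, camera adjusted p = 2.21e-23, and 0.00922 with an estimated correlation). Trem2 did not pass (log2FC -0.48, adjusted p = 0.38).

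In room air, DBA and B6 lungs differed at 8804 genes (3365 higher and 5439 lower in DBA), with at most 2 calls in other splits of the libraries. With Scgb1a1 left out and libraries rescaled 4503 were higher and 4039 lower. Median log2FC of all genes was -0.12, and -0.02 after quantile normalization, so values are read relative to it. In males alone 7358 genes differed. The largest differences included genes known to differ by inheritance. The class II gene H2-Ea-ps, whose start is deleted in the B6 haplotype, was higher in DBA at 124 ± 12.7 against 0.0367 ± 0.0428 TPM (log2FC 6.91, adjusted p = 1.77e-13). Ribosomal protein genes Rpl38 (log2FC 4.35) and Rpl29 (log2FC -6.25) moved in opposite directions, and both have many processed copies to which reads can align. The complement gene C7 (log2FC -5.17, adjusted p = 1.91e-10) and Chil3, a chitinase-like gene of alveolar macrophages (log2FC -5.05, adjusted p = 0.000146), were lower in DBA.

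Alveolar type 2 genes were lower in DBA room-air lung in 9 cases and higher in 1 of 11 (9 and 1 adjusted over the list alone, camera adjusted p = 0.00337, and 0.572 with an estimated correlation). Sftpa1, a surfactant protein gene, stood at 123 ± 33.5 against 976 ± 253 TPM (log2FC -2.98, adjusted p = 5.42e-07) and the phosphate transporter gene Slc34a2 at log2FC -2.30. Airway epithelium genes were higher in 6 of 10 (6 adjusted over the list alone) cases (camera adjusted p = 0.0112, and 0.737 with an estimated correlation). Scgb1a1, the main secretory protein gene of club cells, stood at 68046 ± 34707 against 8543 ± 1581 TPM (log2FC 2.84, adjusted p = 3.66e-05), and took 5.3% to 18.1% of all TPM in DBA libraries. Cell-cycle genes were lower in 25 of 30 (25 adjusted over the list alone) cases (camera adjusted p = 1.75e-06, and 0.572 with an estimated correlation), with Top2a at log2FC -2.08. Alveolar macrophage genes were lower in 10 of 12 (10 adjusted over the list alone) cases (camera adjusted p = 0.00337, and 0.572 with an estimated correlation), among them the scavenger receptor gene Marco (log2FC -2.98, adjusted p = 2.77e-06). Genes of the Trem2-associated lipid and lysosome program were lower in 17 cases and higher in 1 of 20 (17 and 1 adjusted over the list alone, camera adjusted p = 0.00302, and 0.572 with an estimated correlation). Cdkn1a was higher in DBA at 102 ± 37 against 25.7 ± 3.05 TPM (log2FC 1.88, adjusted p = 5.27e-06). Glucocorticoid-responsive genes were higher in 19 of 22 cases (median log2FC 1.25, camera adjusted p = 3.4e-09, and 0.153 with an estimated correlation). Trem2 (log2FC -0.40) and Trp53 (log2FC -0.12) did not pass in room air.

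In hyperoxia DBA and B6 lungs differed at 7196 genes (3639 higher and 3557 lower in DBA), and other splits gave up to 3696 calls. Each strain came from its own date codes, so strain and date code cannot be told apart in either air. Mcpt2 was higher in DBA at 27.5 ± 9.65 against 0.77 ± 0.261 TPM (log2FC 3.94, adjusted p = 1.75e-07). Spink5 was lower at 1.86 ± 0.238 against 80 ± 3.42 TPM (log2FC -4.82, adjusted p = 1.58e-11), and Vipr2, a receptor gene for vasoactive intestinal peptide, by log2FC -3.89. Alveolar macrophage genes were lower in 7 of 12 (7 adjusted over the list alone) cases (camera adjusted p = 0.0101, and 0.919 with an estimated correlation). Glucocorticoid-responsive genes were lower in 14 of 22 cases (median log2FC -0.88, camera adjusted p = 0.000106, and 0.578 with an estimated correlation). Trem2 (log2FC -0.88, adjusted p = 0.0195) and Cdkn1a (log2FC -1.16, adjusted p = 0.000996) were lower in DBA, and Trp53 was higher (log2FC 0.77, adjusted p = 0.000372).

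**Figure D2:**
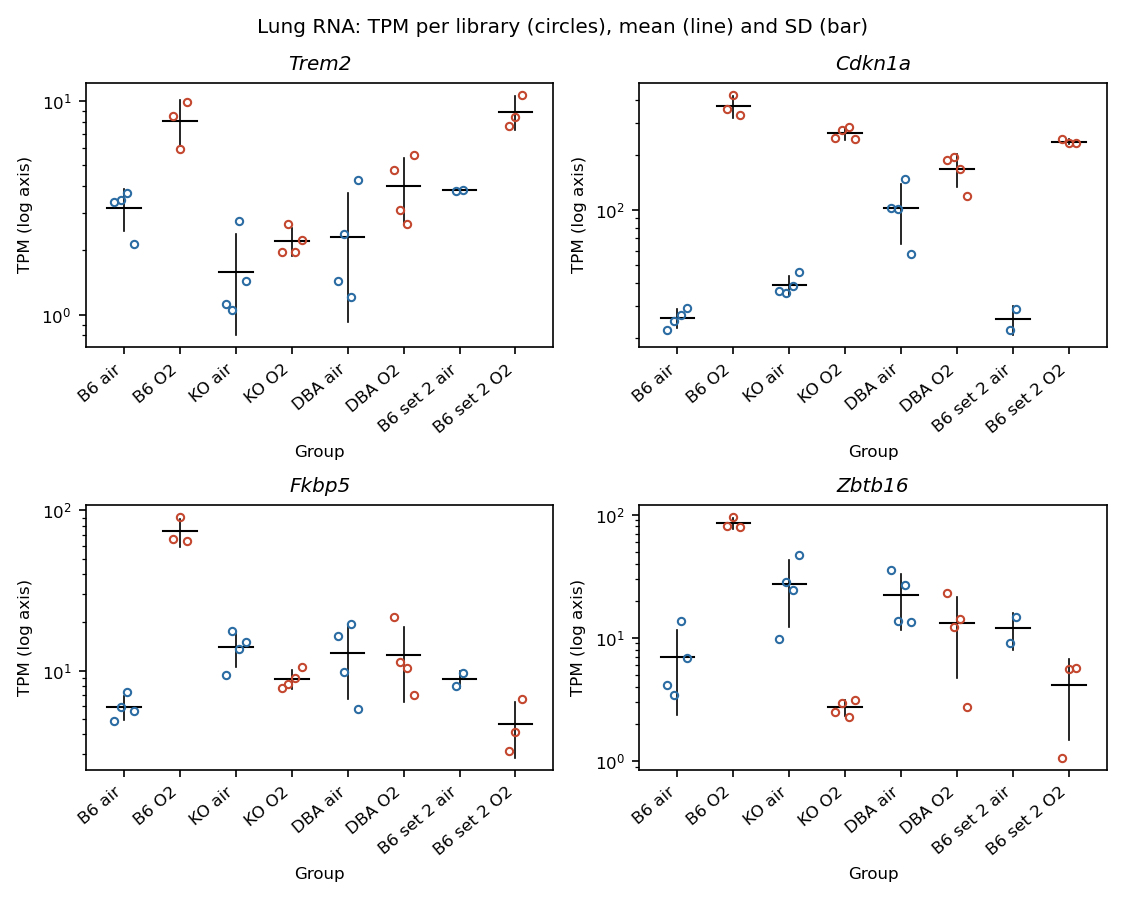
TPM on a log axis in every lung library (circles) of the 8 lung groups for Trem2, Cdkn1a, Fkbp5 and Zbtb16, with the group mean as a line and the SD as a bar. Cdkn1a is higher in oxygen in every genotype, whereas Fkbp5 reaches 74.0 ± 14.6 TPM in the first hyperoxic B6 lungs only.

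Hyperoxic calls were compared between the lung sets to see which changes are common to all genotypes. A core of 125 genes rose and 55 fell in all 4 sets. KO and DBA lungs shared 905 rises and 559 falls, where 312 and 174 would be shared if calls were independent, and 64 genes went opposite ways. B6 and KO lungs shared 669 rises and 698 falls (275 and 370 if independent) with 336 opposite calls. KO and set 2 lungs shared 311 rises and 190 falls (50.9 and 25.0 if independent) with 2 opposite calls. Across genes, which are not independent replicates, log2FC correlated with r = 0.63 between KO and set 2, r = 0.33 between the first B6 lungs and set 2, and r = 0.34 between the first B6 and KO lungs.

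**Figure D3:**
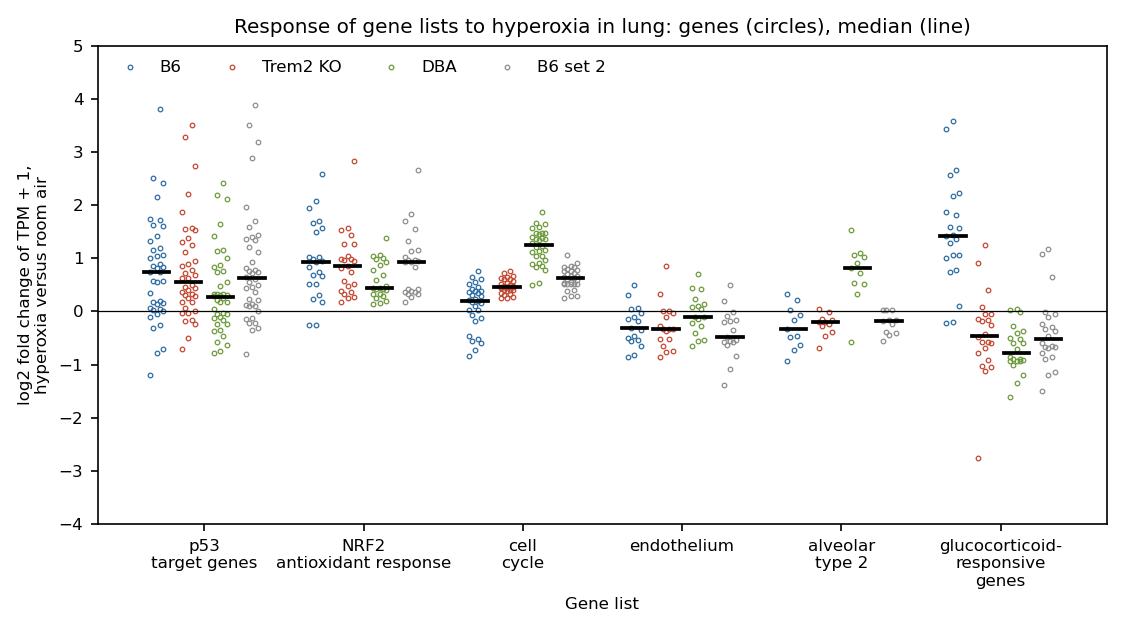
The log2FC of hyperoxia against room air of each member gene (circles) and the median of each list (line) for 6 gene lists in the lungs of B6, KO, DBA and B6 set 2. Medians of p53 targets and NRF2 genes are above 0 in all 4, and the glucocorticoid list has a median of 1.43 in the first B6 lungs and of -0.46 in KO.

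The p53 ChIP-seq lists of lung asked where p53 sits in the tissue under oxygen. Peaks are 200 bp wide intervals on mm10 with the authors' own score, by which peaks are ranked within a list. The hyperoxic B6 lung list held 235 peaks and the room-air list 147, KO lists held 134 and 179, and DBA lists 165 and 255. Of 40 expressed p53 target genes, 13 had a peak within 10 kb of the start site in hyperoxic B6 lung (32.5% against 0.488% of the other genes, Fisher's exact test, two-sided, adjusted p = 2.86e-19). They were Aen, Bax, Bbc3, Cdkn1a, Ckap2, Eda2r, Ei24, Epha2, Mdm2, Phlda3, Plk2, Trp53inp1 and Zmat3. In room-air B6 lung only Bbc3 and Mdm2 had one (2 targets, adjusted p = 0.0104). KO lung gave 4 in hyperoxia (Cdkn1a, Eda2r, Ei24 and Zmat3, adjusted p = 6.68e-05) and 0 in room air, and DBA lung gave 2 in hyperoxia (Bbc3 and Zmat3, adjusted p = 0.0104) and 0 in room air.

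Hyperoxic B6 lung had 2 Cdkn1a peaks, at chromosome 17, 29090822 to 29091022 (-2847 bp from the start site, so upstream, rank 2), and at -1937 bp (rank 49). It had 2 at Mdm2, at -7001 bp (rank 23) and 683 bp (rank 79), and room-air B6 lung had 1 (618 bp, rank 102). The KO hyperoxia list had a Cdkn1a peak at 29090852 to 29091052, also rank 2. Trp53cor1, the gene of the p53-induced noncoding RNA lincRNA-p21, and Klhdc4 had peaks among the 5 highest that can be named in the B6 and KO hyperoxia lists, and Klhdc4 also in room-air B6 (rank 2) and hyperoxic DBA lung (rank 3). Few peaks recurred between lists: 14 of the 134 hyperoxic KO peaks (10.4%) overlapped a hyperoxic B6 peak, and 8 of 235 hyperoxic B6 peaks (3.40%) a room-air B6 peak. The share of tags in peaks was 0.01% to 0.05% in lung, and depth ran from 3.99 M tags in room-air DBA to 33.0 M tags in hyperoxic B6. Replicates are pooled in each list, so no error can be given, and a peak missing from a shallow list is not shown to be absent.

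**Figure D4:**
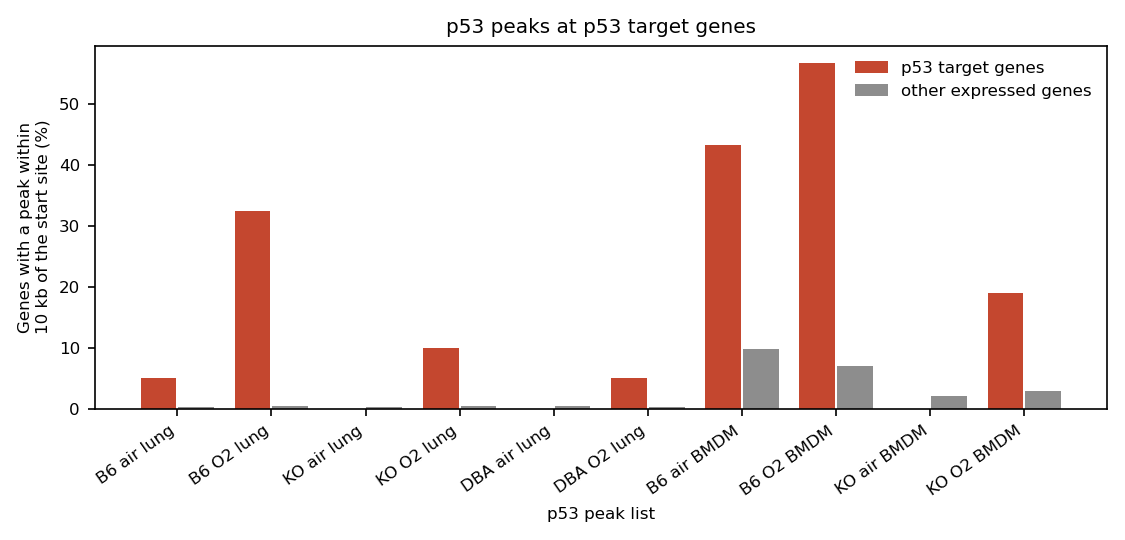
Share in % of p53 target genes and of all other expressed genes with a p53 peak within 10 kb of the start site in each of the 10 peak lists (bars, from 0). The hyperoxic B6 lists stand highest in each tissue, at 32.5% in lung and 56.8% in BMDM, against 10% and 18.9% in KO.

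In culture the question was what oxygen does to the macrophages alone. In B6 BMDM, antioxidant and stress genes rose, and cell-division genes fell as a list with the preset correlation only. Gdf15 rose from 17.3 ± 3.86 to 212 ± 25.1 TPM (log2FC 3.55 ± 0.24 SE, adjusted p = 2.87e-05), with n = 2 and 2, and Cdkn1a rose from 113 ± 17.4 to 300 ± 60.8 TPM (log2FC 1.40 ± 0.13 SE, adjusted p = 0.000128). Of 12320 genes, 3515 passed (700 rose and 2815 fell). The fall of the larger number depends on scaling, since the median of all genes was -0.13 and quantile normalization gave 49.3% rises against 19.9%. With only the B6 groups in the fit 0 genes passed in limma (3647 at unadjusted p < 0.05), so the calls rest on spread estimated from all 12 libraries.

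Other large rises in B6 BMDM were in Cdkn1c, a cell-cycle inhibitor gene (log2FC 2.45), in the glutathione transferase gene Gsta3 (log2FC 2.39), in Rasd2 (log2FC 2.22) and in Gclm, the modifier subunit gene of glutathione synthesis (log2FC 2.13). Falls were led by S100a9 (log2FC -2.89, adjusted p = 0.000295), the mitotic cyclin gene Ccnb2 (log2FC -2.83, adjusted p = 0.000246), Uhrf1, which maintains DNA methylation through replication (log2FC -2.78), Top2a (log2FC -2.53), Tk1 (log2FC -2.51) and Hpgd (log2FC -2.50). Of the NRF2 genes 19 of 21 (21 adjusted over the list alone) rose (camera adjusted p = 4.82e-29, and 0.0328 with an estimated correlation). For the integrated stress response 10 of 14 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 1.83e-12, and 0.00781 with an estimated correlation), and for p53 targets 14 of 37 rose and 5 fell (14 and 6 adjusted over the list alone, camera adjusted p = 2.25e-08, and 0.163 with an estimated correlation). Cell-cycle genes fell in 29 of 30 (29 adjusted over the list alone) cases (camera adjusted p = 4.28e-15, and 0.209 with an estimated correlation) and interferon-response genes in 12 of 19 (15 adjusted over the list alone) cases (camera adjusted p = 0.000937, and 0.434 with an estimated correlation). Trp53 fell by log2FC -0.62 (adjusted p = 0.00391), and Trem2 did not pass (log2FC -0.07, adjusted p = 0.367).

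KO BMDM gave 2868 calls in hyperoxia (848 rose and 2020 fell, with 49.0% rises under quantile normalization against 29.6%), at n = 2 and 2. Antioxidant and stress genes rose here too. Gdf15 rose from 35.6 ± 4.09 to 276 ± 13.6 TPM (log2FC 2.92 ± 0.24 SE, adjusted p = 6.75e-05) and Slc7a11, the cystine importer gene that feeds glutathione synthesis, rose from 0.876 ± 0.0849 to 12.9 ± 0.163 TPM (log2FC 2.89 ± 0.14 SE, adjusted p = 8.65e-06). Srxn1, which repairs oxidized peroxiredoxins, rose by log2FC 2.38, Gclm by 2.25 and Mdm2, the gene of the ubiquitin ligase that limits p53, by 1.15. S100a9 fell by log2FC -2.75, Txnip, a glucose-sensing arrestin gene, by -2.49, and the matrix genes Mgp and Ltbp2 by -2.28 and -2.10. Cdkn1a rose by 1.31 and Trp53 fell with log2FC -0.60. NRF2 genes rose in 20 of 21 (20 adjusted over the list alone) cases (camera adjusted p = 3.33e-28, and 0.0352 with an estimated correlation). Among integrated stress response genes 10 of 14 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 1.61e-12, and 0.00741 with an estimated correlation), and among p53 targets 14 of 37 rose and 4 fell (16 and 6 adjusted over the list alone, camera adjusted p = 5.32e-05, and 0.384 with an estimated correlation). Matrix genes fell in 17 of 18 (18 adjusted over the list alone) cases (camera adjusted p = 4.6e-12, and 0.19 with an estimated correlation). Trem2 did not pass in KO cultures (log2FC 0.06, adjusted p = 0.439).

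DBA BMDM gave 2311 calls (706 rose and 1605 fell, with 47.7% rises under quantile normalization against 30.5%), again at n = 2 and 2. Gdf15 rose from 3.68 ± 1.9 to 23.5 ± 0.852 TPM (log2FC 2.45 ± 0.24 SE, adjusted p = 0.000268), and Ednrb, an endothelin receptor gene, rose by log2FC 2.05. Srxn1 (log2FC 1.84), Slc7a11 (log2FC 1.74) and the mitochondrial one-carbon enzyme gene Mthfd2 (log2FC 1.72) rose as well, and Txnip fell from 669 ± 11.9 to 90.8 ± 0.371 TPM (log2FC -2.87 ± 0.13 SE, adjusted p = 7.92e-06). Cdkn1a rose by log2FC 1.02. NRF2 genes rose in 18 of 21 (20 adjusted over the list alone) cases (camera adjusted p = 1.28e-24, and 0.0489 with an estimated correlation). Of the integrated stress response genes 11 of 14 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 2.94e-11, and 0.01 with an estimated correlation), and of the p53 targets 14 of 37 rose and 2 fell (17 and 7 adjusted over the list alone, camera adjusted p = 6.83e-06, and 0.234 with an estimated correlation). Trp53 fell in DBA cultures (log2FC -0.70, adjusted p = 0.00332), and Trem2 did not pass (log2FC -0.07, adjusted p = 0.395).

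Responses of KO and B6 cultures differed for 179 genes (81 positive, 98 negative), and with only these 4 groups in limma's fit for 0 (2163 at unadjusted p < 0.05). Division genes were on the positive side, because they fell less in KO, from a lower room-air level: Uhrf1 (log2FC 1.91, adjusted p = 0.015), the proliferation marker gene Mki67 (log2FC 1.85, adjusted p = 0.0203) and the mitotic kinase gene Plk1 (log2FC 1.66). Cell-cycle genes were higher in the KO response in 7 of 30 (27 adjusted over the list alone) cases (camera adjusted p = 3.94e-20, and 0.308 with an estimated correlation). The DBA and B6 cultures differed for 120 genes (52 positive, 68 negative), and for 0 with only their 4 groups in limma's fit (1539 at unadjusted p < 0.05). Csf1, the macrophage growth factor gene, had the largest negative difference (log2FC -1.82, adjusted p = 0.0364). Hpgd, which breaks down prostaglandins, had a positive one (log2FC 1.31, adjusted p = 0.0291), from a lower room-air level in DBA. Most matrix genes are near 0 TPM in B6 cultures in both airs and cannot show a fall there, so their negative differences in both interactions are not read as a different response. None of the fixed genes passed: Trem2 (log2FC 0.13), Trp53 (log2FC 0.02) and Cdkn1a (log2FC -0.08) for KO, and Trem2 (log2FC -0.002), Trp53 (log2FC -0.07) and Cdkn1a (log2FC -0.37) for DBA.

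In room air KO and B6 cultures differed at 6052 genes (4173 higher and 1879 lower in KO, with 51.4% higher under quantile normalization against 69.0%). Median log2FC of all genes was 0.14, so single values are read relative to that. Matrix genes nearly silent in B6 were expressed in KO. Bgn, the gene of the proteoglycan biglycan, stood at 85 ± 15.4 against 0.415 ± 0.0219 TPM (log2FC 5.91, adjusted p = 2.35e-08) and the collagen gene Col1a2 at 53.2 ± 8.52 against 0.126 ± 0.0361 TPM (log2FC 5.58, adjusted p = 2.35e-08). Dcstamp, which macrophages need to fuse, was lower at 0.294 ± 0.196 against 23.2 ± 8.37 TPM (log2FC -4.19, adjusted p = 3.06e-06). Folr2 (log2FC -3.84), S100a4 (log2FC -3.63) and the urokinase gene Plau (log2FC -3.57) were lower as well. Lpl, the lipoprotein lipase gene of the Trem2-associated program, was lower by log2FC -3.39. Matrix genes were higher in 17 of 18 (17 adjusted over the list alone) cases (camera adjusted p = 4.12e-11, and 0.351 with an estimated correlation). Cholesterol synthesis and efflux genes were lower in 11 of 15 (11 adjusted over the list alone) cases (camera adjusted p = 2.36e-08, and 0.351 with an estimated correlation). Cell-cycle genes were lower in 30 of 30 (30 adjusted over the list alone) cases (camera adjusted p = 8.86e-21, and 0.351 with an estimated correlation). Trp53 (log2FC -0.12) and Cdkn1a (log2FC -0.14) did not pass.

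In hyperoxia 6194 genes differed between KO and B6 cultures (4690 higher, 1504 lower, 51.5% higher under quantile normalization against 75.7%, median 0.19). Bgn (log2FC 4.61), the fibronectin gene Fn1 (log2FC 4.09) and Timp1, a metalloproteinase inhibitor gene (log2FC 3.69), were higher in KO, and the fatty-acid desaturase gene Fads2 lower (log2FC -3.31). Cholesterol genes were lower in 12 of 15 (12 adjusted over the list alone) cases (camera adjusted p = 1.12e-11, and 0.409 with an estimated correlation). B6 cultures carry their own date code, so genotype and date code cannot be told apart in either air. Trem2 was lower in hyperoxic KO cultures (log2FC -1.88, adjusted p = 9.94e-08), while Trp53 (log2FC -0.10) and Cdkn1a (log2FC -0.22) did not pass.

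DBA and B6 cultures differed at 7003 genes in room air and 7462 in hyperoxia (71.6% and 76.9% higher in DBA, 51.4% and 50.4% under quantile normalization, medians 0.19 and 0.26). Ifi202b, a DNA-sensor gene that B6 mice barely express, was higher at 383 ± 101 against 0.0245 ± 0.0346 TPM (log2FC 8.53, adjusted p = 1.18e-09) in room air. Gpnmb, whose DBA/2J allele carries a premature stop, was lower at 88.5 ± 1.8 against 4489 ± 1374 TPM (log2FC -5.61, adjusted p = 3.44e-08). Bgn (log2FC 5.33) and Col1a2 (log2FC 5.31) were higher in DBA cultures too. Matrix genes were higher in 17 of 18 (17 adjusted over the list alone) cases in room air (camera adjusted p = 4.36e-08, and 0.443 with an estimated correlation). Cholesterol genes were lower in 13 of 15 (13 adjusted over the list alone) cases in room air (camera adjusted p = 2.25e-09, and 0.443 with an estimated correlation) and in 13 of 15 (13 adjusted over the list alone) in hyperoxia (camera adjusted p = 4.53e-11, and 0.267 with an estimated correlation). Trem2 passed in room air with log2FC 0.15 (adjusted p = 0.0251), which is below the median of all genes. Trem2 in hyperoxia (log2FC 0.15, adjusted p = 0.0253) was below that median too. Trp53 (log2FC 0.04) and Cdkn1a (log2FC 0.12) did not pass in room air, nor did Trp53 (log2FC -0.04) and Cdkn1a (log2FC -0.25) in hyperoxia.

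The BMDM ChIP-seq lists held 4107 p53 peaks in room-air and 3500 in hyperoxic B6 cultures, and 1263 and 1320 in KO. Of 37 expressed p53 targets, 21 had a peak within 10 kb in hyperoxic B6 cultures (56.8% against 7.04% of other genes, Fisher's exact test, two-sided, adjusted p = 1.67e-14) and 16 in room air (43.2% against 9.72%, adjusted p = 3.96e-07). KO cultures gave 7 in hyperoxia (Bax, Bbc3, Ccng1, Cdkn1a, Mdm2, Psrc1 and Zmat3, 18.9% against 2.92%, adjusted p = 0.000184) and 0 in room air. The KO lists had fewer tags in peaks (0.25% and 0.23% against 0.76% and 0.64%), were called against the B6 input per the file headers, and come from samples titled as knockout whose genotype label reads C57BL/6J. The fewer KO targets are therefore a difference between lists, not a tested difference in binding.

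Bbc3, which encodes the apoptosis inducer PUMA, had the highest peak that can be named in hyperoxic B6 cultures (chromosome 7, 16308597 to 16308797, at -886 bp from the start site, rank 3). Cdkn1a had a peak at chromosome 17, 29090839 to 29091039, in both B6 lists (rank 14 in room air, 5 in hyperoxia), a second at -1943 bp in hyperoxia (rank 47), and 1 at -2849 bp in hyperoxic KO cultures (rank 22). Mdm2 had a peak at chromosome 10, 117717649 to 117717849, in hyperoxic B6 and KO cultures alike, 1 at -6995 bp in room-air B6 (rank 19) and a second at 671 bp in hyperoxic B6 (rank 113). A peak at the Trem2 start site itself (chromosome 17, 48346301 to 48346501) was listed in hyperoxic B6 cultures with rank 566. Room-air B6 cultures had one 8000 bp downstream of the start, and no KO or lung list had any within 10 kb. In room-air KO cultures 19 of the 20 highest peaks had no start site within 10 kb, and the highest that can be named lay at Mir101c and Pisd-ps3. Of hyperoxic peaks, 298 (8.51%) overlapped a room-air peak in B6 and 49 (3.71%) in KO, and 115 of the 1320 hyperoxic KO peaks (8.71%) overlapped a hyperoxic B6 peak. Genes with a hyperoxic B6 peak within 10 kb rose in 86 of 886 cases (9.71%, against 5.37% of other genes) and fell in 211 (23.8% against 22.8%), and as a list they did not pass in B6 BMDM (median log2FC -0.11 against -0.14, limma camera, unadjusted p = 0.289). In KO 38 of 366 rose (10.4% against 6.78%) and 39 fell (10.7% against 16.6%, limma camera, unadjusted p = 0.0704).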

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

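The 2 tests of the glucocorticoid pattern and the look at set 2 beside the interactions were chosen after the result was seen, and the divisions of libraries were planned before the data were examined.

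In the lungs, the responses of KO and B6 to oxygen differed by an interaction test for 3955 genes, and those of DBA and B6 for 4563. Genotype labels were moved among libraries within each exposure, in 100 relabellings with the real one included. For KO and B6 no other relabelling reached 3955 (highest other 3617). For DBA and B6, 2 of 100 reached the real count, the real one included. The other one called 5533 genes with only 5 of 15 labels right, a count that strain differences can enter. These relabellings therefore cannot exclude chance for the DBA and B6 count. Genotype and date code go together in both.

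Genes whose response differed between KO and B6 were Zbtb16 (difference in log2FC -6.34), Fkbp5 (-4.01), Pdk4 (-3.77), Fam107a (-3.60) and Cdkn1a (-1.07), lower in KO. Higher were Nr4a1 (3.65), Meox2 (2.42), Cxcl5 (2.39), Il33 (2.36), Oasl2 (1.93) and Trp53 (0.87). Between DBA and B6 they were Zbtb16 (-4.48), Pdk4 (-3.56), Fkbp5 (-3.44), Klf15 (-3.18) and Cdkn1a (-3.04), lower in DBA, and Slc27a6 (3.37), Mcm2 (2.19) and Trp53 (0.89), higher. Set 2 moved like the first B6 lungs for 49.1% of their calls where KO differed and 55.6% where DBA did. Elsewhere it was 80.6% and 74.2%. Of differing genes called in both sets 76 of 119 and 132 of 176 did so. No difference is read as genotype alone. Single genes went both ways: Cxcl5 rose in set 2 (log2FC 3.91) as in KO, and Nr4a1 fell (-1.12) as in the first B6. As lists, the glucocorticoid-responsive genes differed in KO (camera adjusted p = 3.69e-19) and in DBA (2.21e-23), and both calls held with an estimated correlation (0.0219 and 0.00922). Interferon-response genes in KO (0.00156), and cell-cycle genes (1.2e-10) and p53 targets (0.000962) in DBA, passed as lists with the preset correlation only.

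The glucocorticoid-responsive genes rose with oxygen in the first B6 lungs (median log2FC 1.43) and not in KO lungs (median -0.46). A difference of line would need set 2 to rise too. Its median was -0.52, on the side of KO, which argues against the line as the whole cause. A batch by date code, or sex, would end the rise among libraries of the same code and sex. Among male B6 libraries of the first date code the median was 1.66, which argues against both within B6. An event shared by the first hyperoxic B6 mice, such as stress, fasting or collection hour, may have raised these genes. It would not explain these genes' higher medians in room-air KO and DBA than B6 lungs. It stays open: the sources name no such event, and no biological cause besides line and sex was tested.

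In BMDM the responses of KO and B6 differed for 179 genes and those of DBA and B6 for 120. Between KO and B6 they included Uhrf1 (1.91), Mki67 (1.85) and Plk1 (1.66), and the cell-cycle list (camera adjusted p = 3.94e-20, and 0.31 with an estimated correlation). Between DBA and B6 they included Hpgd (1.31) and Csf1 (-1.82). Most matrix genes are near 0 TPM in B6 cultures, which fixes the sign of their difference, so they are left out. Divisions of the libraries were not run for these counts.

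Single lung libraries lay far from the others of their group of 4 in 17 of 244 sets of values tested (6.97%), and chance gives about 1 in 20, so these are few more than chance would give. No library was far in more than 2 sets. In room-air B6 lung they were low values of Aplnr (84.3 TPM), Ciart (10.8 TPM) and Nr4a3 (0.533 TPM) and high values of Gclc (44.4 TPM), Scgb1a1 (10909 TPM), Slc27a6 (105 TPM) and Slc7a10 (45.7 TPM). In room-air KO lung they were low Atf3 (2.10 TPM) and Ptprb (136 TPM) and high Gclc (57.6 TPM), Nr4a3 (9.21 TPM), Ntrk2 (19.0 TPM) and Pdgfra (130 TPM). One hyperoxic KO library was high in Krt18 (117 TPM). DBA lungs had high C7 (8.67 TPM) and Hspa1b (22.2 TPM) in room air and high Chil3 (29.7 TPM) in hyperoxia, the last against 2.47 to 4.65 TPM in the other libraries.

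Other divisions of the libraries into groups of the same sizes made chance unlikely for the simple lung comparisons. With 35 divisions they cannot exclude it. Of 35 divisions each, only the real 1 reached the count for hyperoxia in B6 (6662, highest other 2787), in KO (3079, highest other 1) and in DBA (4841, highest other 105). The same held for KO against B6 in room air (12, highest other 1) and hyperoxia (5814, highest other 1432) and for DBA against B6 in room air (8804, highest other 2) and hyperoxia (7196, highest other 3696). For KO or DBA against B6 the real division also follows date codes, in full except for KO against B6 in room air, so it does not separate genotype from date code.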

How the results depend on the processing

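Alternatives by date code, sex, the MF and F marks, leaving out Scgb1a1 and the block on numbers 1 and 2 were chosen after the data were seen, and the others were planned. No called gene named in the text and no list test that passed changed direction under any alternative run. The larger side of the calls did change in several comparisons, so it is not a finding there. With Scgb1a1 left out and libraries rescaled, DBA lung gave 2109 rises and 2568 falls, and DBA against B6 in room air 4503 higher and 4039 lower. Quantile normalization gave 1626 rises and 1663 falls in KO lung, and 3411 higher and 3736 lower for DBA against B6 in hyperoxia, where no filter on low values gave 3555 and 3763. Males alone gave 47 higher and 57 lower for KO against B6 in room air. The BMDM interactions turned too: without B6 room-air F they gave 182 positive and 82 negative (KO) and 147 and 61 (DBA), and the DBA one also with a pseudocount of 0.1 (5 and 4) and without DBA room-air 1 (5 and 2) or 2 (129 and 69). All counts of genes not given below stayed within 1.5 times their value.

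A minimum absolute log2FC of 1 lowered nearly every count, since it asks for more. It left 898 genes in B6 lung, 215 in KO lung, 427 in DBA lung and 300 in set 2. The lung interactions kept 782 (KO) and 1271 (DBA). KO against B6 lung kept 4 in room air and 533 in hyperoxia, and DBA against B6 kept 1850 and 1267. In BMDM the counts were 386 (B6), 336 (KO), 274 (DBA) and 61 (DBA minus B6), and 1128 and 872 for KO and 1395 and 1466 for DBA against B6 in room air and hyperoxia. Genes called the same way in a pair of lung sets were then 101 (B6 and KO), 56 (B6 and DBA), 47 (KO and DBA), 94 (B6 and set 2), 104 (KO and set 2) and 63 (DBA and set 2).

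Without a filter on low values, which tests more genes, KO against B6 lung in room air gave 1, set 2 gave 272 and the KO minus B6 BMDM interaction 275. A pseudocount of 0.1 left 9 genes in each BMDM interaction. Neither cause was tested. Quantile normalization moved KO against B6 lung in room air to 19. With only the groups of a comparison in the fit, limma gave 1 there, 4533 for KO BMDM, 0 for B6 BMDM (3647 at unadjusted p < 0.05) and 0 for the KO minus B6 and DBA minus B6 BMDM interactions (2163 and 1539 at unadjusted p < 0.05). These rest on fewer degrees of freedom.

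The third date code alone gave 1905 in KO lung, and the fourth alone 1788 in DBA lung, or 0 with no other group in the fit (limma, 3947 at unadjusted p < 0.05). For KO against B6 lung in room air the second date code alone gave 0 (limma, 1073 at unadjusted p < 0.05), males alone 104 and a sex term 23. The DBA minus B6 interaction gave 2940 in males alone. As a replicate block, shared numbers gave 2407 in KO BMDM and 2347 in DBA BMDM, and numbers 1 and 2 gave 1171 in set 2. With these blocks 144 and 145 list tests passed, against 146. With a correlation estimated per list 11 list tests passed.

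With each library left out in turn, a lone remaining library is assumed to vary like the other groups. Counts ran from 5657 to 6287 in B6 lung, 2114 to 2980 in KO, 3620 to 5415 in DBA, 3411 to 3903 in the KO and 3586 to 5243 in the DBA interaction. KO against B6 gave 4983 to 5220 in hyperoxia, and DBA against B6 7989 to 8873 in room air and 6216 to 6910 in hyperoxia. KO against B6 BMDM gave 4418 to 5387 and 4490 to 5401, and DBA against B6 BMDM 6015 to 6696 and 6000 to 6708. List tests past the threshold ran from 138 to 151.

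KO against B6 lung in room air ran from 1 to 23. It was 2 and 1 without the first and second B6 library of the first date code, 19 without the second B6 library of the second code, 23 and 1 without the KO libraries of the second code, and 1 without either KO library of the third. Set 2 ran from 123 to 705: it was 187 and 123 without room-air replicates 1 and 2, and 350 and 404 without hyperoxia replicates 1 and 3. B6 BMDM ran from 1966 (without room-air MF) to 3546, with 2333 without hyperoxia F. KO BMDM ran from 1331 to 1467, with 1467 and 1331 without room-air replicates 1 and 2 and 1417 and 1430 without hyperoxia replicates 1 and 2. DBA BMDM ran from 984 to 1923, with 1522 without room-air replicate 2 and 1126 and 984 without hyperoxia replicates 1 and 2. The KO minus B6 BMDM interaction ran from 0 to 264. It gave 0 in limma without KO room-air 1, KO hyperoxia 1 or KO hyperoxia 2 (1447, 1556 and 1309 at unadjusted p < 0.05), 55 without KO room-air 2, and 45, 47 and 48 without B6 room-air MF, hyperoxia MF and hyperoxia F. The DBA minus B6 one ran from 0 to 208. It gave 0 without DBA hyperoxia 1 or 2 (1891 and 1384 at unadjusted p < 0.05), 7 and 198 without DBA room-air 1 and 2, 19 and 208 without B6 room-air MF and F, and 8 and 50 without B6 hyperoxia MF and F.

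Peaks at or above the median score of a tissue were 5 (B6 room air), 111 (B6 hyperoxia), 10 (KO room air) and 38 (KO hyperoxia) in lung and 1750 and 1598 in B6 BMDM. With scores above the tissue median, shares of overlapping peaks were 33.3% (KO with B6) and 0% (DBA with B6) in room-air lung, 36% (KO with B6) in hyperoxic lung, 16.1% and 7.53% (hyperoxia with room air in B6 and KO BMDM), and 9.87% and 16.9% (KO with B6 BMDM in room air and hyperoxia). Fewer peaks enter these, and scores follow depth (all 255 peaks of room-air DBA, at 3.99 M tags, lie above the median), so this threshold does not treat the lists alike. Within 50 kb, 2 p53 targets had peaks in room-air B6 and 2 in hyperoxic DBA lung and no longer passed, since more other genes have one. Genes with a hyperoxic KO BMDM peak within 1 kb passed (limma's camera, unadjusted p = 0.0165 over 24 genes, against 0.0704 within 10 kb), but not with an estimated correlation (0.274).

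Small changes are often missed: at a true log2FC of 0.5 simulated data of the set 2 design recovered 6% of genes.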

Other observations

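The tests of explanations in this part were chosen after the patterns were seen, and what the leave-out of Scgb1a1 would show was written before its result. In hyperoxic B6 lung, macrophage genes moved apart rather than together. Marco, a scavenger receptor gene of alveolar macrophages, rose from 11.6 ± 3.65 to 36.4 ± 18.4 TPM (log2FC 1.51 ± 0.40 SE, adjusted p = 0.00664), while Ccr2, the receptor gene that brings monocytes in from blood, fell from 12 ± 2.32 to 3.67 ± 0.571 TPM (log2FC -1.46 ± 0.18 SE, adjusted p = 1.28e-05). Alveolar macrophage genes as a list went both ways (3 of 12 rose and 5 fell, 4 and 5 adjusted over the list alone, camera adjusted p = 0.918). Hopx, a gene of alveolar type 1 cells, rose from 398 ± 40.3 to 659 ± 38.6 TPM (log2FC 0.73 ± 0.12 SE, adjusted p = 0.000137), and Vegfa, the vascular growth factor gene those cells express, fell from 398 ± 23.1 to 246 ± 5.47 TPM (log2FC -0.69 ± 0.09 SE, adjusted p = 3.62e-05). Among targets of HIF, a transcription factor controlled by oxygen, the mitophagy gene Bnip3 rose by log2FC 1.29 and the collagen-modifying enzyme gene P4ha1 fell by -1.14. At the Trem locus, Nfya, which encodes a general transcription factor subunit and lies beside the Trem genes, fell from 41.6 ± 1.78 to 13.2 ± 0.626 TPM (log2FC -1.58 ± 0.08 SE, adjusted p = 5.64e-09), and Treml4 fell by log2FC -1.32.

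In cultures under oxygen, interferon-response genes fell in 16 of 19 (18 adjusted over the list alone) cases in KO (camera adjusted p = 4.78e-08, and 0.384 with an estimated correlation) and in 12 of 19 (15 adjusted over the list alone) in DBA (camera adjusted p = 6.83e-06, and 0.446 with an estimated correlation). Genes for MHC class II fell in 5 of 5 (5 adjusted over the list alone) cases in B6 cultures (camera adjusted p = 0.00274, and 0.374 with an estimated correlation). The hyperoxic lungs of set 2 showed a fall of heart-muscle genes in 2 of 6 (5 adjusted over the list alone) cases (camera adjusted p = 0.000265, and 0.285 with an estimated correlation), where the first B6 lungs had a rise of Myh6.

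Room-air DBA lungs had lower alveolar type 2 genes and higher airway genes than B6 lungs. Very abundant Scgb1a1 lowers other TPM in a library, but with it left out and libraries rescaled the type 2 median was -1.66, close to -1.82 with it, which argues against it as the cause. More airway and less alveolar tissue would lower type 1 genes alike. Their median was -0.31, and type 1 and type 2 genes differed by 1.51 (permutation test over 21 genes, two-sided, p = 0.00833), which argues against that mix alone. Since 0 B6 libraries share a date code with DBA, batch and strain cannot be told apart, and a lower type 2 program in DBA may contribute.

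KO cultures had higher stromal and matrix genes than B6 cultures. If only loss of Trem2 raised these genes, KO would exceed DBA cultures, which carry Trem2. The KO minus DBA median was 0.20, against 3.07 for KO minus B6, which argues against it as the only cause. An effect in KO stays open. A candidate source is stromal cells in the KO and DBA cultures. Of a second stromal list 94.7% (18 of 19) were higher in KO than in B6. Col1a2 read 0.126 TPM in B6, 53.2 in KO and 43.9 in DBA in room air, and Sparc 0.151, 34.7 and 30.9 TPM, while the macrophage gene Lyz2 read 20133, 16091 and 15786 TPM and Csf1r 883, 1276 and 951 TPM. With 0 B6 cultures of the date code of the others, culture batch and genotype cannot be told apart.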
